A study of Rattus norvegicus with 6 samples.

How the data were processed

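The series holds 6 arrays of the Agilent Rat GE 4x44K v3 design, 1 colour, with RNA of left ventricle from 3 OLETF and 3 LETO rats. The groups, replicate numbers and ages were taken from the labels, with replicate numbers from the titles. The source name of LETO 2 reads replicate 1, and the numbers of the LETO files differ from those of the titles. Strain is the same in all of these, and statements about single LETO arrays follow the titles. Per the file headers the arrays were read with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.1. The scanner files hold spot signal as linear intensity, per the file headers, with the background already subtracted and detrended in the processed signal. The deposited value table holds linear intensity divided by a constant per array near its 75th percentile, so the scale is not log2 and no centring was applied. Its column medians were 0.163, 0.154 and 0.158 in LETO and 0.154, 0.157 and 0.159 in OLETF, and the correlation of its logarithms with the processed signal of the scanner files was 1.0000. With 1 colour there is no direction of a ratio to check.

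The processed signal was log2 transformed, and the 75th percentile of each array over all non-control probes was subtracted. Control spots and spots with a feature outlier flag, between 260 and 356 per array, were left out, which removed 17 probes altogether. Spots of the same probe were averaged on the log2 scale. A probe was tested if it was well above background on all 3 arrays of at least 1 strain, which left 21484 of 30367 probes. The tested probe with the highest mean signal stood for each of the 26456 gene names in the files that had one, which gave 18816 genes. Positions are those of the rn4 build in the files, without conversion. The RefSeq table was used for names only, and 18387 probes, or 60.5%, were matched to it through an accession. Of 1074 list symbols 1042 were found in the files.

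Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at default settings and Benjamini-Hochberg adjustment over all genes tested at 0.05. Shifts of gene lists were tested with camera at a preset correlation of 0.01 over 50 of 51 lists with at least 5 measured genes, 35 of pathways and 16 of cell type markers. Camera with an estimated correlation and fry, directional and mixed, were run beside it. Tables were read with the data.table package, version 1.17.8, and Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

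The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the largest change in each direction among called genes with a symbol that were well above background on all 6 arrays. It adds up to 5 called genes per direction that were above background in all arrays of 1 strain and in none of the other. From each list it takes up to 4 called members, or up to 2 given as values only where none was called. It also takes 9 genes whatever their values, which are Cckar, Ampd3, Xdh, Pdk4, Nppa, Nppb, Myh6, Myh7 and Slc2a4. An item that the rule takes is not reported here. Genes outside the rule are marked in the text as chosen after their values were seen.

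The alternatives were quantile normalization, scaling to the median of probes above background on all arrays, normexp background correction with an offset of 50 followed by quantile normalization, and the value table. Further alternatives were no filter on dim probes, a filter on all 6 arrays, the mean of all probes of a gene, every probe on its own, and eBayes with trend and robust. Array quality weights, treat with a fold of 1.5, an adjusted p below 0.01, a replicate block, age as a covariate, slide as a block, and leaving out each array in turn completed the list. The replicate block was not used in the main test because the rats of the strains share only a number, and the correlations of the deviations within the numbers were −0.09, −0.14 and −0.01.

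The scripts were tested on simulated data with 18816 genes and 3 arrays per group, with 50 genes changed at each fold. The share recovered was 36% at 1.5-fold, 78% at 2-fold, 88% at 4-fold and 96% at 8-fold, with 3 unchanged genes called. The shifted list was called, and 0 of the lists that share no gene with it were. The simulated genes were drawn independently, so this does not test false list calls among correlated genes. Single outlying values within a group were not tested with 3 arrays per group, and the array quality weights were 0.206, 1.02 and 2.94 in LETO 1 to 3 and 0.934, 0.736 and 2.37 in OLETF 1 to 3.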

Results

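Gene expression was measured in left ventricle of 6 male rats with 1-colour arrays, 1 array per rat. OLETF is an inbred rat strain that develops obesity and type 2 diabetes, and LETO is its non-diabetic control strain. Per the labels there were 3 independent experiments per strain, so the p-values measure the spread between samples. The rats were 27 or 28 weeks old. Each array held 42877 spots for 30367 different probes. The share of spots well above background lay between 75.55% and 79.80%, and no spot was saturated. The 75th percentile of the signal lay between 1271 and 1827 intensity units. All 3 LETO arrays and OLETF 1 lay on 1 slide, and OLETF 2 and OLETF 3 lay on another, so strain and slide were partly mixed. The first principal component held 42.9% of the variance and separated the strains, and the second held 23.8% and set LETO 1 apart. The array quality weight of LETO 1 was 0.206, the lowest of the 6. The number of arrays limits the precision.

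The comparison of OLETF with LETO asks which transcripts of the ventricle differ between a rat with type 2 diabetes and its control, although strain and diabetes cannot be separated in this design. Of 18816 genes tested, 283 were higher and 197 were lower in OLETF. Akr1b10, an aldo-keto reductase, was 22.5-fold higher, and Serhl2, a serine hydrolase-like protein, was 9.60-fold higher. Cd300lg, a receptor of capillary endothelium, was 20.3-fold lower, and Map3k12, a stress-pathway kinase, was 10.3-fold lower. Akr1b10, Serhl2 and Map3k12 had no other tested probe, and the second probe of Cd300lg gave a smaller log2 change of −2.04. For the genes with the largest changes, a second probe is given below wherever it was tested. As groups, immediate early genes and lymphocyte markers were shifted down, and interferon response genes, antigen presentation genes, genes responsive to PPAR-alpha, genes of fatty acid oxidation and neutrophil and mast cell markers were shifted up. None of these list shifts passed with an estimated correlation between genes. The natriuretic peptide genes Nppa and Nppb and the glucose transporter gene Slc2a4 did not pass.

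Akr1b10 (rn4 chromosome 4, 61771202 to 61771261) rose from −5.14 ± 0.04 in LETO to −0.65 ± 0.14 in OLETF (SD, n = 3 each, log2 of signal over the array's 75th percentile). This was a log2 change of 4.49 ± 0.10 (SE, adjusted p = 9.67e-06). Serhl2 (chromosome 7, 121146515 to 121146574) rose from −1.72 ± 0.03 to 1.55 ± 0.03, a log2 change of 3.26 ± 0.08 (adjusted p = 9.67e-06). Within the first slide alone, with slide as a block, the log2 change was 4.39 for Akr1b10 and 3.30 for Serhl2. Slc4a1, the anion exchanger of red blood cells, rose by 3.19 ± 0.36 on the log2 scale (adjusted p = 0.00593), and its value with slide as a block was 2.88 (adjusted p = 0.117). Tnni1, the slow skeletal troponin I that the fetal heart also uses, rose by 1.98 ± 0.33 (adjusted p = 0.0258), and with slide as a block its value was 1.55 (adjusted p = 0.343). Its call was also lost without LETO 2, LETO 3, OLETF 2 or OLETF 3.

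The other large increases were of mixed function. Folr2, a folate receptor of macrophages, rose by 1.94 ± 0.11 on the log2 scale (adjusted p = 0.000314), and Dgkg, a diacylglycerol kinase, rose by 1.90 ± 0.10 (adjusted p = 0.000245). Ogn, a small proteoglycan of the matrix, rose by 1.72 ± 0.18 (adjusted p = 0.00468). Tsks, known from testis, rose by 1.86 ± 0.13 (adjusted p = 0.00088). Klre1, a natural killer cell receptor, rose by 1.80 ± 0.22 (adjusted p = 0.0083). These 5 genes stayed called with slide as a block, with log2 changes of 1.79 for Folr2, 1.85 for Dgkg, 2.07 for Ogn, 1.68 for Tsks and 2.24 for Klre1. Ccr10, a chemokine receptor, rose by 1.87 ± 0.17 (adjusted p = 0.0022), and with slide as a block its value was 1.68 (adjusted p = 0.0531).

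Cd300lg (rn4 chromosome 10, 91121069 to 91121128) went from 2.40 ± 0.44 in LETO to −1.95 ± 0.17 in OLETF (SD, n = 3 each) and so fell by 4.34 ± 0.22 on the log2 scale (SE, adjusted p = 0.000245). A second probe of Cd300lg gave −2.04, so the size of its decrease depends on the probe. Map3k12 (chromosome 7, 141255682 to 141255741) went from 1.78 ± 0.09 to −1.58 ± 0.09 and fell by 3.36 ± 0.09 (adjusted p = 1.42e-05). C2, a complement component (chromosome 20, 4071119 to 4071178), fell by 3.52 ± 0.22 (adjusted p = 0.000608), and its second probe gave −3.58. Snrpb, a core protein of the spliceosome, went from 4.96 ± 0.08 to 2.89 ± 0.07 and fell by 2.08 ± 0.09 (adjusted p = 0.000129). The values with slide as a block were −4.50 for Cd300lg, −3.46 for Map3k12, −3.70 for C2 and −2.09 for Snrpb, and all 4 stayed called.

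Pbld, an isomerase-like protein, fell by 2.72 ± 0.12 on the log2 scale (adjusted p = 0.000129), and Tdrd1, a germ-cell protein, fell by 2.24 ± 0.17 (adjusted p = 0.00113). The chemokine Ccl20 fell by 1.96 ± 0.17 (adjusted p = 0.00195), and its second probe gave −2.16. Ctu1, an enzyme of transfer RNA modification, fell by 2.70 ± 0.19 (adjusted p = 0.000938), but its second probe gave 0.28, so the decrease of the transcript is uncertain. The slide block gave −2.66 for Pbld, −2.38 for Tdrd1, −1.76 for Ccl20 and −2.90 for Ctu1, and all 4 stayed called. Adh1, an alcohol dehydrogenase, fell by 2.32 ± 0.42 (adjusted p = 0.0388), its value with slide as a block was −1.57 (adjusted p = 0.406), and its call was lost without LETO 1, LETO 2, OLETF 2 or OLETF 3. Ly49i2, a natural killer cell receptor, fell by 2.39 ± 0.23 (adjusted p = 0.00316), and with slide as a block its value was −2.37 (adjusted p = 0.0679). Ly49 genes are near-identical relatives, so which of them the probe measured is uncertain.

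**Figure D1:**
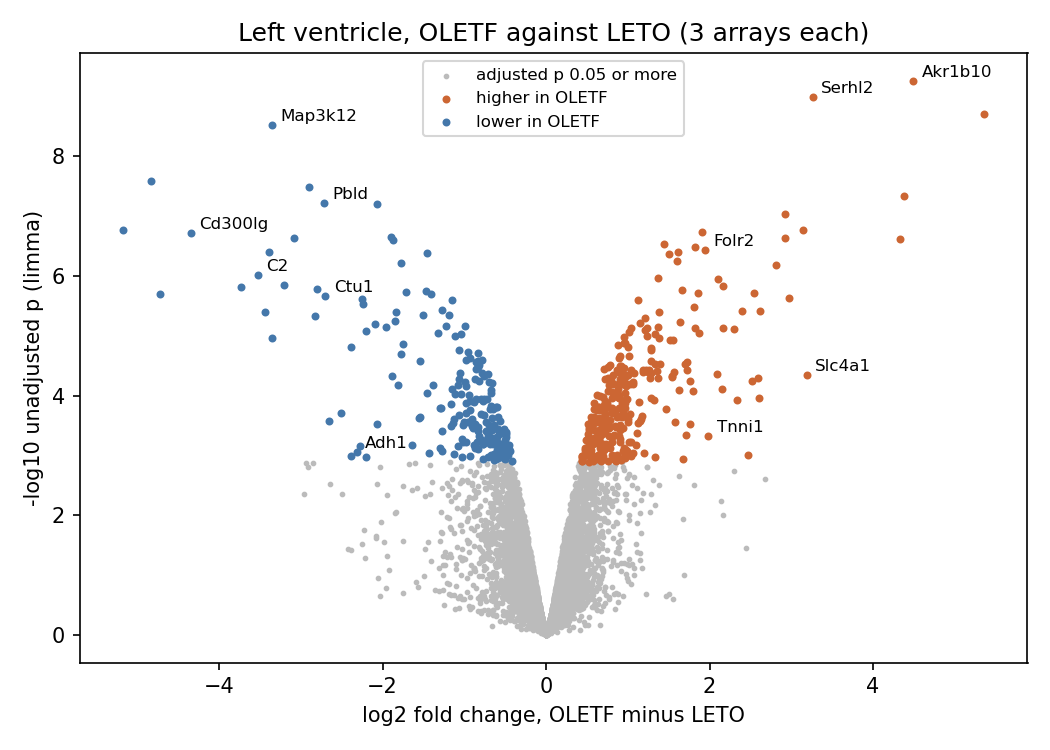
The horizontal axis gives the log2 change of OLETF over LETO and the vertical axis −log10 of the unadjusted p-value, with 1 point per gene and n = 3 arrays per strain. The 283 genes called higher and the 197 called lower are coloured, with Akr1b10 at 4.49 and Cd300lg at −4.34.

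**Figure D2:**
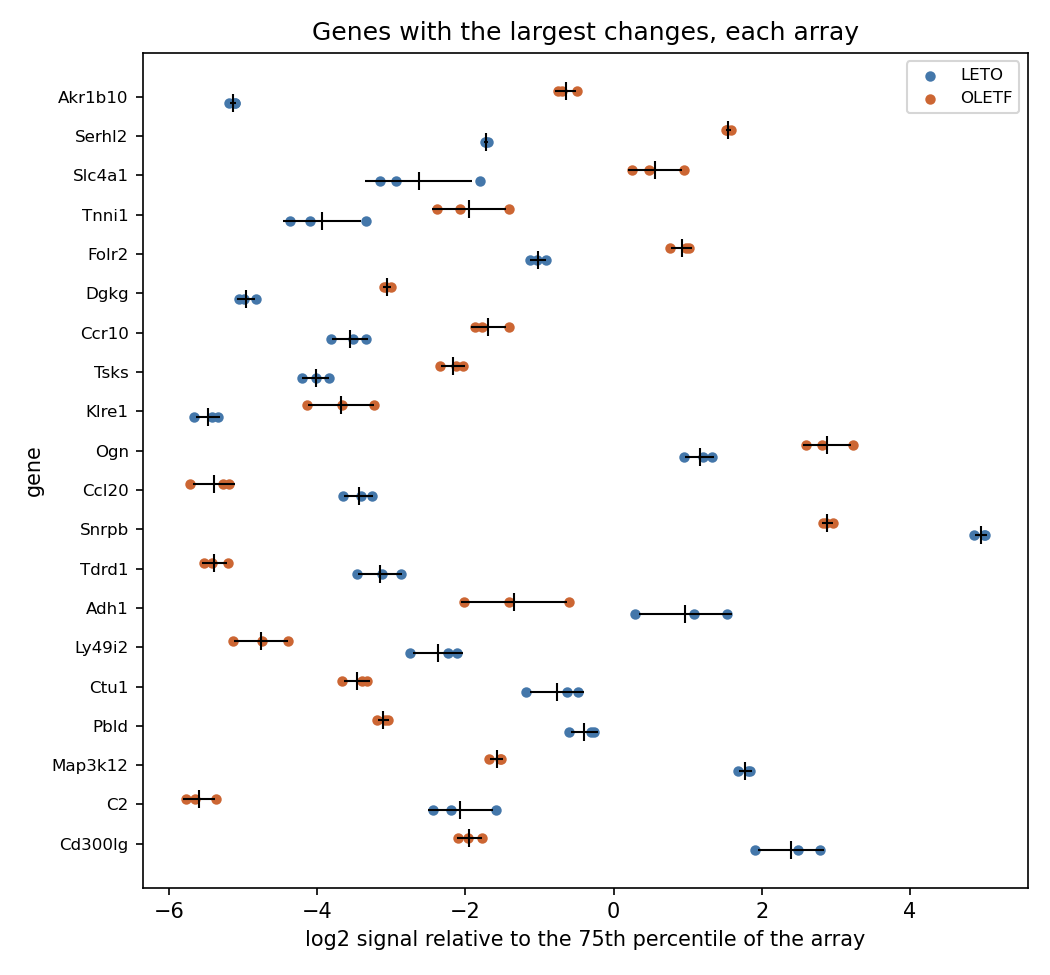
Each point is 1 array, on a horizontal axis of log2 signal over the array's 75th percentile, for the genes with the largest changes on the vertical axis, with ticks at the strain means and bars of 1 SD (n = 3). The strains do not overlap for Akr1b10, whose means are −5.14 in LETO and −0.65 in OLETF, nor for Map3k12, whose means are 1.78 and −1.58.

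Some changed genes were well above background in 1 strain only, 14 in LETO and 15 in OLETF. For these the bound is the mean signal in the strain that has the gene over the signal of the dim strain, where any signal below the array's floor was raised to that floor, the lowest signal of a probe well above background. Klk10, a kallikrein-related peptidase, was at least 8.11-fold lower in OLETF (adjusted p = 0.00242), and the ribosomal pseudogene Rpl27-ps1 was at least 8.43-fold lower (adjusted p = 0.000823). Ly49i3 was at least 7.66-fold lower (adjusted p = 0.000245) and Ly49i9 at least 2.72-fold lower (adjusted p = 0.000314). These 4 genes were not well above background in OLETF, and all 4 stayed called with slide as a block, with adjusted p = 0.0142 for Klk10, 0.00266 for Rpl27-ps1, 0.00654 for Ly49i3 and 0.00909 for Ly49i9. Slc47a1, a transporter of organic cations, was at least 4.10-fold higher in OLETF (adjusted p = 0.00195), and Scrn1, a secernin, at least 2.86-fold higher (adjusted p = 0.00663). The F-box protein Fbxl2 was at least 2.03-fold higher (adjusted p = 0.000651), the receptor Gpr123 at least 1.98-fold higher (adjusted p = 0.00563) and the lipid transfer protein relative Gltpd2 at least 1.84-fold higher (adjusted p = 0.0103). These 5 genes were not well above background in LETO. Slc47a1 and Fbxl2 stayed called with slide as a block, and Scrn1, Gpr123 and Gltpd2 did not. The log2 values with the block were 2.52 for Scrn1, 1.24 for Gpr123 and 1.20 for Gltpd2, against 2.52, 1.25 and 0.99 without it. These values use LETO signal that was not well above background, so they do not measure the size of the change. The call of Gltpd2 was also lost without 1 of the 6 arrays.

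Immediate early genes, which respond within minutes to growth and stress signals, had negative values for all 23 members measured, and the list was shifted down by a median of −0.81 on the log2 scale (camera adjusted p = 1.93e-09, adjusted p = 0.767 with an estimated correlation). No member passed on its own, and 0 passed adjusted over the list alone. Jun had a value of −0.81 (adjusted p = 0.137). Nr4a3, a nuclear receptor of this group, had −2.96 (adjusted p = 0.101), with an SD of 1.57 within OLETF, and its second probe gave −0.84. Their values with slide as a block were −0.36 for Jun and −1.27 for Nr4a3. The arrays differed within strains, with list medians of 0.61, −0.28 and −0.35 in LETO 1 to 3 and −0.35, −1.33 and −0.95 in OLETF 1 to 3. Within the first slide the median was −0.35, and with slide as a block the list stayed called. That difference rests on LETO 1, since OLETF 1 lay level with LETO 2 and LETO 3.

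Interferon response genes were shifted up, with a median of 0.40 and positive values for 19 of 22 members (camera adjusted p = 2.05e-06, adjusted p = 0.756 with an estimated correlation). Stat2, a transcription factor of interferon signalling, rose by 0.72 (adjusted p = 0.00644), and the interferon-induced gene Ifi27 rose by 0.75 (adjusted p = 0.0188). Both were no longer called with slide as a block, with values of 0.68 for Stat2 (adjusted p = 0.142) and 0.62 for Ifi27 (adjusted p = 0.305), and Ifi27 was also lost without LETO 3, OLETF 2 or OLETF 3. The other 20 did not pass over all genes, and 6 members rose adjusted over the list alone. Within the first slide the list median was 0.32, and with slide as a block the list stayed called (adjusted p = 0.000514).

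Antigen presentation genes were shifted up by a median of 0.35, with positive values for 16 of 20 members (camera adjusted p = 9.53e-06, adjusted p = 0.767 with an estimated correlation). Over all genes 3 members rose, and 10 rose adjusted over the list alone. The 3 were the class I genes RT1-CE10 at 0.67 (adjusted p = 0.0253), RT1-CE5 at 0.67 (adjusted p = 0.0388) and RT1-S3 at 0.63 (adjusted p = 0.0463). These are related class I genes, so which of them rose is uncertain, and another probe of RT1-CE5 gave 1.27. None of the 3 stayed called with slide as a block, where their values were 0.53, 0.53 and 0.52, and each was lost without at least 4 of the 6 arrays in turn. Within the first slide the list median was 0.23, and with slide as a block the list stayed called (adjusted p = 0.000514).

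Lymphocyte markers were shifted down by a median of −0.30, with negative values for 10 of 13 members (camera adjusted p = 0.00018, adjusted p = 0.727 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, fell by 0.96 (adjusted p = 0.0177), and Nkg7, a protein of cytotoxic granules, fell by 0.84 (adjusted p = 0.0219). Adjusted over the list alone 6 members fell. The slide block gave −0.70 for Cd3g (adjusted p = 0.237) and −0.80 for Nkg7 (adjusted p = 0.286), the list median within the first slide was −0.18, and the list was no longer called (adjusted p = 0.265). Without OLETF 1 the list median was −0.51. Both genes were lost without at least 4 of the 6 arrays in turn.

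Neutrophil and mast cell markers were shifted up by a median of 0.40, with positive values for 7 of 10 members (camera adjusted p = 0.0443, adjusted p = 0.727 with an estimated correlation). Cpa3, a carboxypeptidase of mast cells, rose by 1.03 (adjusted p = 0.0146), and 4 members rose adjusted over the list alone. Cpa3 was well above background on 2 of 3 LETO arrays, and with slide as a block its value was 1.07 (adjusted p = 0.181), and it was lost without LETO 3 or any of the 3 OLETF arrays. The list call was lost when only genes above background on all 6 arrays were used (median 0.03, adjusted p = 0.296), without LETO 2 (adjusted p = 0.0638), without OLETF 2 (adjusted p = 0.158) and with slide as a block (adjusted p = 0.332). The median within the first slide was 0.08, and without 1 array it ranged from 0.17 without OLETF 2 to 0.67 without LETO 1. Quantile normalization, median scaling and normexp gave adjusted p = 0.0748, 0.0673 and 0.0568.

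Genes responsive to PPAR-alpha were shifted up by a median of 0.19, with positive values for 16 of 20 members (camera adjusted p = 0.0133, adjusted p = 0.727 with an estimated correlation). No member passed over all genes, and 0 passed adjusted over the list alone. Pdk4, the kinase that restrains glucose oxidation, had 0.89 ± 0.36 (SE, adjusted p = 0.372), the receptor Ppara had 0.52 (adjusted p = 0.0805) and the lipid droplet gene Adfp, now named Plin2, had 0.41 (adjusted p = 0.238). Their values with slide as a block were 0.44 for Pdk4, 0.63 for Ppara and 0.21 for Adfp. The list was lost without LETO 3 (adjusted p = 0.0719) and with slide as a block (median 0.21 within the first slide, adjusted p = 0.101).

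Fatty acid uptake and beta-oxidation genes were shifted up by a median of 0.11, with positive values for 19 of 25 members (camera adjusted p = 0.0443, adjusted p = 0.885 with an estimated correlation). None passed over all genes, and 0 passed adjusted over the list alone. The mitochondrial isomerase Eci1 had 0.26 (adjusted p = 0.386) and the carnitine carrier Slc25a20 had 0.19 (adjusted p = 0.406), and with slide as a block they had 0.36 and 0.23. The list stayed called with slide as a block (median 0.16 within the first slide, adjusted p = 0.00122). It was lost without LETO 1 (median 0.01, adjusted p = 0.665), without OLETF 1 (adjusted p = 0.278) and with array weights (adjusted p = 0.336).

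**Figure D3:**
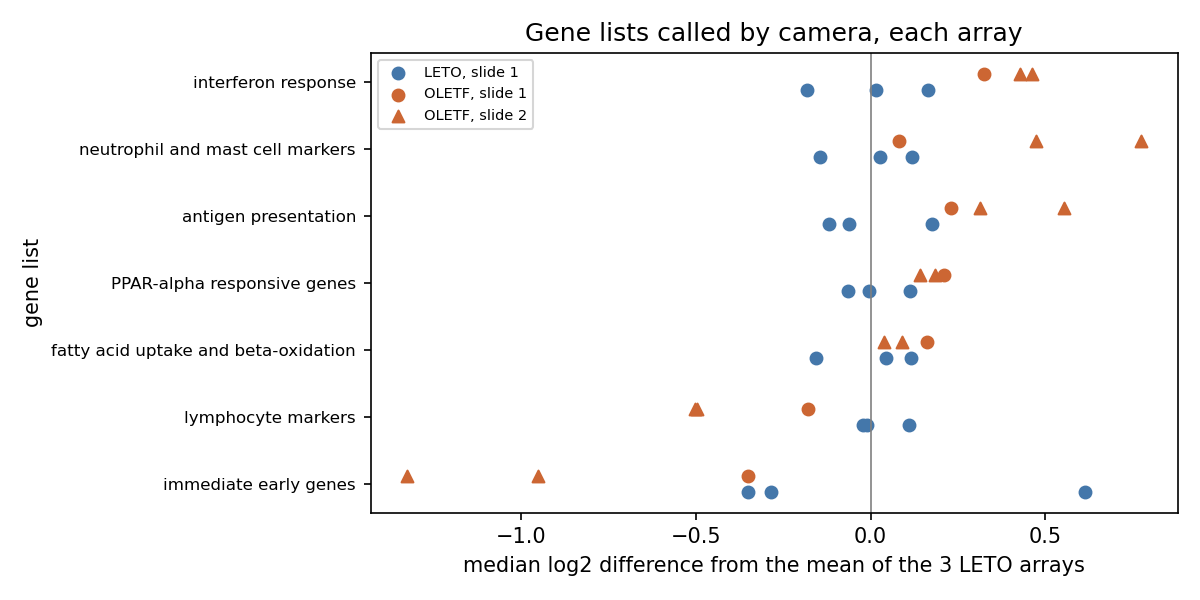
Each point is 1 array, on a horizontal axis of the list's median log2 difference from the mean of the 3 LETO arrays, for the called gene lists on the vertical axis, with triangles for the second slide. Immediate early genes range from 0.61 in LETO 1 to −1.33 in OLETF 2, and interferon response genes lie between 0.32 and 0.46 in the 3 OLETF arrays.

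Antioxidant and NRF2-responsive genes were not shifted as a list, with a median of −0.02 and a mean of 0.04 over 34 members (camera adjusted p = 0.857). Akr1b8, an aldo-keto reductase, rose by 1.72 (adjusted p = 0.00554). Its probe, at 61724364 to 61725032 on rn4 chromosome 4, lies near that of Akr1b10, so the rises of these related genes may not be independent. Mt1a, a metal-binding metallothionein now named Mt1, rose by 1.70 (adjusted p = 0.00494), and Gstm2, a glutathione transferase, fell by 0.93 (adjusted p = 0.0108). With slide as a block Mt1a stayed called at 1.94 (adjusted p = 0.0393), whereas Akr1b8 had 1.66 (adjusted p = 0.104) and Gstm2 had −0.72 (adjusted p = 0.169). Adjusted over the list alone 3 members rose and 4 fell. Among 14 oxidases that produce reactive oxygen, Nox4 rose by 1.71 (adjusted p = 0.0247), with 2 of 3 LETO arrays above background, and Ncf1, a subunit of the phagocyte oxidase, fell by 0.58 (adjusted p = 0.0428). Both were lost with slide as a block, at 1.47 for Nox4 and −0.63 for Ncf1. Gstm2, Nox4 and Ncf1 were each lost without at least 2 of the 6 arrays in turn.

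Among 26 genes of glucose uptake and glycolysis, Eno1, an enolase, rose by 0.81 (adjusted p = 0.0087), and its other probes gave 0.87 and 0.95. The median of that list was −0.01 and its mean 0.05 (camera adjusted p = 0.519). Of 39 nuclear-encoded respiratory chain genes 35 had negative values with a median of −0.05 (camera adjusted p = 0.112), and without LETO 1 that list was called at −0.15 (camera adjusted p = 1.33e-06). Uqcrfs1, the iron-sulfur subunit of complex III, fell by 0.66 (adjusted p = 0.00686). Acadsb, a dehydrogenase of branched-chain amino acid breakdown, fell by 1.02 (adjusted p = 0.0188), and Lss, an enzyme of cholesterol synthesis, fell by 0.60 (adjusted p = 0.0365). In insulin signalling Pik3r1, a regulatory subunit of PI3-kinase, rose by 0.83 (adjusted p = 0.0245), while the glucose transporter Slc2a4 had −0.15 (adjusted p = 0.716). With slide as a block none of these was called, with values of 0.70 for Eno1, −0.61 for Uqcrfs1, −0.90 for Acadsb, −0.54 for Lss, 1.05 for Pik3r1 and 0.02 for Slc2a4. Uqcrfs1 was lost without 1 of the 6 arrays, and Acadsb, Lss and Pik3r1 without at least 4.

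Of the purine degradation genes Aox1, an aldehyde oxidase, rose by 1.02 (adjusted p = 0.0302), while xanthine dehydrogenase, Xdh, had 0.31 (adjusted p = 0.584) and the deaminase Ampd3 had −0.05 (adjusted p = 0.979). Trib3, a pseudokinase induced by endoplasmic reticulum stress, rose by 0.75 (adjusted p = 0.0195). Of 21 inflammatory mediators only Casp1, the inflammasome protease, changed, with a rise of 0.64 (adjusted p = 0.0214), while 16 had negative values and the list median was −0.34 (camera adjusted p = 0.14). Within the first slide that median was 0.07, and without LETO 1 it was −0.14 (camera adjusted p = 0.906). The list was called without LETO 3 (−0.76, camera adjusted p = 0.00148) and without OLETF 1 (−0.54, camera adjusted p = 0.00662). Psma2, a proteasome subunit, fell by 0.83 (adjusted p = 0.00463), and Npr3, the natriuretic peptide clearance receptor, fell by 1.43 (adjusted p = 0.0404). Of 33 matrix genes only Col6a1, a collagen VI chain, changed, with a rise of 0.89 (adjusted p = 0.00686). Lyve1, a marker of lymphatic vessels and of resident macrophages, fell by 1.55 (adjusted p = 0.0158). With slide as a block Col6a1 stayed called at 1.04 (adjusted p = 0.048), and the other values were 1.01 for Aox1, 0.83 for Trib3, 0.51 for Casp1, −0.77 for Psma2, −1.06 for Npr3 and −1.03 for Lyve1. Npr3 was lost whichever of the 6 arrays was left out, Trib3 without 5 and Aox1, Casp1 and Lyve1 without 4 of the 6 in turn.

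The natriuretic peptides Nppa and Nppb did not pass, with −0.30 (adjusted p = 0.921) and −0.65 (adjusted p = 0.519), nor did the myosin heavy chains Myh6 and Myh7, with −0.06 (adjusted p = 0.952) and −0.10 (adjusted p = 0.847). The slide block gave −0.63 for Nppa, −1.09 for Nppb, −0.17 for Myh6 and −0.16 for Myh7. Without LETO 1 Nppa had 0.24 and Nppb −0.29. The fetal and hypertrophy-associated list had a median of −0.16 over 20 members (camera adjusted p = 0.14), with Tnni1 as its 1 called member. Cckar, the cholecystokinin receptor known to be deleted in OLETF, had 0.15 (adjusted p = 0.735) and lay at −5.14 in LETO and −4.98 in OLETF. Its probe was well above background on all 6 arrays, and the files do not say whether it lies in the deleted part, so the value does not check the strain labels.

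Markers of other cell types were measured beside these groups. Red blood cell markers had a median of −1.45 with 7 of 8 negative values (camera adjusted p = 0.0905), and their array medians were 0.21, 0.51 and −0.67 in LETO 1 to 3 and −1.08, −1.61 and −1.65 in OLETF 1 to 3. Without LETO 3 the list was called at −2.17 (camera adjusted p = 0.000264). Within that list Slc4a1 rose, while Hbb, a globin gene chosen for mention after its values were seen, had −2.22 ± 0.95 (SE, adjusted p = 0.41) with an SD of 2.04 within LETO and a value of −1.36 with slide as a block. Globin genes are near-identical, so the value may not belong to Hbb alone. Endothelial markers had a median of 0.07 (camera adjusted p = 0.954), smooth muscle and pericyte markers −0.08 (camera adjusted p = 0.0905), with Acta2 at −0.44 (adjusted p = 0.238), and macrophage markers 0.07 with a mean of −0.07 (camera adjusted p = 0.979). Within the first slide these medians were −0.06, −0.10 and −0.06. Without LETO 1 the smooth muscle list was called at −0.14 (camera adjusted p = 0.0354) and the macrophage list at 0.16 (camera adjusted p = 0.0444). Fibroblast markers had a median of 0.08 (camera adjusted p = 0.237) and were also called without LETO 1, at 0.19 (camera adjusted p = 0.00986).

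The calls came from limma with adjustment over all 18816 genes, and 2337 genes had an unadjusted p below 0.05. The strains did not overlap in 3263 genes, or 17.3%, where 10% is expected by chance. Of the 480 changed genes 190 differed by a fold of 2 or more, and 83 of these were lower. Of 49 changed genes with other tested probes, 38 had all of them in the same direction, but only 21 had at least 1 of them called the same way. With slide as a block, which compares OLETF 1 with the 3 LETO arrays, 52 genes were higher and 51 lower. OLETF 2 and OLETF 3 against OLETF 1 gave 0 calls with limma, with 578 genes at an unadjusted p below 0.05. Both comparisons rest on OLETF 1 as a single array, with the spread taken from the other arrays, so the 0 calls do not show that the slide had no effect. Of the 50 lists tested 7 were called with camera, and 0 with an estimated correlation or with directional fry, and other splits of the 6 arrays gave up to 15 with camera. The mixed fry test, which looks for change in either direction, called 25 lists.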

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

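The cause of the differences between settings was not tested. With no filter on dim probes 149 genes were higher and 91 lower, with treat 45 and 40, and with an adjusted p below 0.01 121 and 79. Array weights gave 857 and 801, with 16 lists. Slide as a block, which leaves 3 degrees of freedom, gave 52 and 51 with 4 lists, and 93 of the 480 genes stayed called. Leaving out 1 array gave 128 to 375 higher, 87 to 239 lower and 7 to 13 lists. The circadian clock list was not called with all arrays (median −0.26, camera adjusted p = 0.0535). It was called without LETO 2, LETO 3 or OLETF 1, but not without LETO 1, OLETF 2 or OLETF 3. Age as a covariate gave 11 lists. With an estimated correlation or with directional fry 0 lists were called. Other scalings kept between 403 and 474 of the 480 genes, and all of these kept their direction. Below the level well above background a log2 change was not measured, and the bounds are only lower limits.

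With a replicate block 166 genes were higher and 13 lists were called. The samples share only a number, the correlations of the deviations were −0.09, −0.14 and −0.01, and across the strains only LETO 1 and OLETF 3, not every sample, correlated best with the sample of their own number.

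Directions turned only for genes that were not called. Myh6, at −0.06, was 0.056 with quantile normalization, 0.0445 with normexp and 0.0345 with age, and ranged from −0.15 without OLETF 2 to 0.0112 without LETO 2. Myh7 was 0.0001 with quantile normalization and 0.0127 with normexp. Nppa was 0.37 with array weights and ranged from −0.71 without LETO 3 to 0.24 without LETO 1. Ampd3 was 0.10 with age and 0.0512 with slide as a block, and ranged from −0.40 without LETO 1 to 0.13 without LETO 3. Slc2a4 was 0.0151 with slide as a block. Without 1 array Nppb ranged from −0.89 to −0.29, Pdk4 from 0.55 to 1.21, Xdh from 0.12 to 0.46, Hbb from −3.37 to −1.40 and Cckar from 0.09 to 0.23. Lymphocyte markers ranged from −0.51 without OLETF 1 to −0.22 without OLETF 2. Among the called lists, PPAR-alpha responsive genes were lost without LETO 3, fatty acid oxidation without LETO 1 or OLETF 1, and neutrophil and mast cell markers without LETO 2 or OLETF 2.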

Other observations

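Calls lay close together at several places of the genome, and genes named here only for their position were chosen after their values were seen. On rn4 chromosome 4 between 166862652 and 168892920, in the natural killer receptor complex, 8 of 20 tested genes changed, with Klre1 and Klrc3 higher and Ly49i2, Ly49i3 and Ly49i9 among the 6 that were lower. On chromosome 1 between 93814007 and 95561902, which holds kallikrein genes, 11 of 67 changed, with Klk10, Ctu1 and Nkg7 among the 10 that were lower and Tsks the 1 that was higher. On chromosome 20 between 2757558 and 4071149, in the major histocompatibility region, 8 genes were higher, RT1-CE10, RT1-CE5 and RT1-S3 among them, and 1, C2, was lower. On chromosome 4 between 76783971 and 77466050 5 of 16 were higher, among them Gimap4, Gimap5, Gimap6 and Gimap7, which encode GTPases of lymphocytes. Receptors, kallikreins and class I genes of these regions are close relatives, so the calls are not independent. Other genes named above also lay in such groups, and further groups are not described. On chromosome 10, 5 of 64 changed, with Ccr10 and Slc4a1 among 4 higher and Cd300lg the 1 lower. On chromosome 7, 5 of 25 changed around Serhl2, with 2 higher, and 4 of 14 around Map3k12, with 2 higher. Around Mt1a on chromosome 19, 5 of 14 changed, and around Trib3 on chromosome 3, 4 of 13 changed, all higher.

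The tests of endothelial cells, smooth muscle cells, macrophages and lymphocytes, and neutrophils or mast cells were chosen after the list results were seen, and so was the choice of the immediate early and interferon patterns. The intervals around the ratios and the 3 ways of counting neighbours were added after the results were seen as well.

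For the 480 calls between the strains, the 10 splits of the 6 arrays are too few for a share below 0.1, and the real split gave 480 genes against at most 0 in another, while for lists it gave 7 against up to 15, and 8 of 10 splits gave as many. The slide is an unlikely source of most of the 417 genes called from OLETF 2 and 3 against LETO 2 and 3. They kept a median of 0.72 of their log2 change (95% interval 0.667 to 0.777) between OLETF 1 and LETO 1 on 1 slide. Of the 417, 364 had the same direction there, and 82 had a ratio below 0.25. The 480 calls themselves were not tested in this way. The median ratio rests on 1 array of each strain, and the array weight of LETO 1, 0.206, was the lowest. Strain variants under the probes may account for part of the calls with a fold of 2 or more, since other probes of 23 genes gave a median of 0.47 of the change (0.0945 to 0.874), an interval too wide to tell. The genes differed widely, with ratios from −0.218 to 1.62, and 10 of the 23 lay below 0.25. Regions that differ between the strains could account for part as well, since 55.75% of the 452 calls with a position had another call within 1 Mb against 42.15% in a permutation test (p = 0.0001), and 49.83% against 36.6% among genes with a symbol (permutation p = 0.0002). Related genes lie together, and with 1 gene kept per name stem the share was 42.91% against 32.95% when stems were thinned within 1 Mb (permutation p = 0.0034), but permutation p was 0.051 per chromosome, 0.062 in the genome and 0.39 for calls with a fold of 2 or more, so this stays open. Neighbouring calls did not share a direction more often than permuted directions. With stems thinned within 1 Mb, 30 of 63 adjacent pairs had the same direction, against a permuted mean of 31.85 (one-sided permutation p = 0.726).

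A single array alone is unlikely to be the whole source of the lower immediate early genes. Without LETO 1, the array that mattered most, 0.71 of the median was left (95% interval 0.513 to 0.85). The slide could account for part of the decrease. OLETF 1 alone showed 0.434 of the shift (0.242 to 0.56), and the interval keeps this open. LETO 1 and the slide together were not tested and stay open as a joint source. The list median of OLETF 1, −0.35, lay level with −0.28 in LETO 2 and −0.35 in LETO 3, whereas LETO 1 had 0.61. Fewer endothelial cells in the OLETF pieces are an unlikely source, with an endothelial marker median of 0.0661 (−0.11 to 0.12). When single arrays were left out, that median ranged from 0.0001 without LETO 3 to 0.12 without OLETF 1. Fewer smooth muscle cells stay open as a source, since the marker median of −0.0784 had an interval (−0.44 to 0.01) that reaches −0.40, the level set for this test as 0.5 of the shift. The mean of these markers was −0.25, and single markers ran from −0.85 to 0.05. Handling of the tissue before freezing, the strain and the diabetes all could change these genes and were not tested.

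For the higher interferon response genes, more macrophages and lymphocytes are an unlikely source on these markers. The higher of their marker medians was 0.0731 (95% interval −0.09 to 0.11). This lay below 0.20, the level set for this test as 0.5 of the shift. Without LETO 1 the macrophage median was 0.16, nearer to that level but still below it. Only 2 of the 22 genes lie on chromosome 20, so the 1.0000 of the median that the others kept could not have fallen below 0.93, and this does not test a part of the major histocompatibility region. More neutrophils or mast cells stay open, since their marker median was 0.395 (−0.09 to 1.27). A single array could account for part, since 0.685 of the median was left (0.389 to 0.905) without LETO 3, and the interval keeps this open. The strain and the diabetes were not separated by any test here, so either could be the source. Chance also stays open for this shift and for that of the immediate early genes, since 8 of the 10 splits, the real split among them, gave at least 7 lists.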
